A study of Mus musculus with 4 samples.

How the data were processed

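Messenger RNA was measured in mature neutrophils sorted from mouse bone marrow, 2 WT samples and 2 Srf KO samples, grouped by the genotype in the labels. Libraries were made from total RNA with the Illumina TruSeq RNA v2 kit, per the labels' protocols, a kit that does not keep the strand, so reads of overlapping and antisense genes cannot be told apart. CASAVA 1.8.1, TopHat2 2.0.0, Cufflinks 2.0.0 and the mm10 build are named per the submitters' processing notes, without their settings. The 4 tables used hold genes, isoforms, transcription start site (TSS) groups and coding sequences, 1 row each, in the layout of a Cufflinks difference test, per the file headers.

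Expression is given in FPKM as the authors deposited it, 1 value per genotype and not per sample. The log2 fold is WT over KO per the file headers, and its sign was turned here to Srf KO over WT. Where a group was at 0 the authors' log2 fold holds a placeholder, and no fold was used for those genes. The test statistic is a score deposited by the authors, and the p-value and q-value beside it are theirs too. It was checked on all 4 tables that the p-value is the two-sided normal tail of the statistic, that the q-value is its Benjamini-Hochberg adjustment over rows of status OK, and that the authors' call is a q-value of at most 0.05. Of the 23284 genes, 12634 had status OK; 10467 were not tested for too few reads, 151 had low data, 26 failed and 6 had too many reads. Per-sample values were not used here, so depth, the spread between replicates, an analysis without each sample and an estimated correlation between genes could not be had. Gene-level differences were meant to be tested from per-sample values had the tables held them; with pooled values the authors' own test is the main result.

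The implied standard error is the absolute log2 fold divided by the absolute statistic, available for 12552 genes. Its median was 0.24 and its minimum 0.18. The smallest absolute log2 fold called was 0.43, and genes with larger standard errors needed larger folds. A p-value listed as 0 occurs for 130 genes, and the smallest above 0 is 2.22e-16. Starts in the tables count from 0 and are printed counting from 1. Of 20800 symbols matched to GENCODE M21 (GRCm38, the assembly of mm10), 99.5% were on the same chromosome. Exon numbers, strand and Ensembl identifiers come from that annotation.

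A total of 28 gene lists were fixed before the data were examined, of which 27 had at least 3 tested members. They cover SRF targets of actin and immediate-early type, SRF and its cofactors, actin turnover, adhesion, chemotaxis, 3 neutrophil maturation groups, NADPH oxidase, interferon, inflammation, apoptosis, proliferation, heat shock, ribosomal and mitochondrial genes, sex-linked genes and 9 other cell types. Each was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the authors' statistic signed by the fold, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Calls in each list were also counted with the p-values adjusted over the list alone and compared by two-sided Fisher's exact tests. The list median was set against 10000 random lists matched on mean expression in 20 bins. Named genes were Srf, the 10 called genes with the largest fold in each direction among those above 0 in both groups and at 1 FPKM or more in one, up to 4 members per list, up to 3 called genes at 0 in one group, and up to 3 features per direction called in uncalled genes. Actb and Actg1 stand outside this rule. The results of 1 list and of some genes that the rule picked are not reported here, though the list is included in every number of lists given.

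Transcript length was taken from GENCODE for the isoform with the highest FPKM, with a value for 98.5% of genes with a fold. Folds were adjusted by subtracting their running median over 50 length bins, smoothed over 5 bins, and p-values were recomputed with the same standard errors. A second adjustment removed the trend on expression as well. Alternatives were other thresholds, filters at 1 and 5 FPKM, a 2-fold minimum, folds on the log2(FPKM + 1) scale with a pseudocount of 1, centred folds, lists left out, other preset correlations and other windows around Srf. The length adjustments, the removal of X and Y and the lists without Srf were added after seeing the data.

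The test was tried on simulated data, with 12552 genes of the real standard errors for Srf KO against WT. Of 100 genes changed 2-fold 64 were recovered and of 100 changed 1.41-fold 12, with 2 false calls. A planted list of 40 genes had a cameraPR adjusted p of 8.76e-10 and an unchanged list 0.406. Errors were drawn as independent and normal with those standard errors taken as true, and a far smaller share of genes was changed than the data call. The simulation therefore does not show how well the authors' test is calibrated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.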

Results

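RNA was sequenced from mature mouse bone marrow neutrophils whose genotype was labelled WT or Srf KO. The gene Srf encodes serum response factor (SRF), a transcription factor that binds CArG boxes and drives many genes of the actin cytoskeleton. The cells had been sorted on high Gr1, high 7/4 antigen and high side scatter, which together mark granular neutrophils. There were 2 WT samples and 2 Srf KO samples, 4 in total, and the title of the series places the comparison in the question of whether neutrophils need SRF to migrate during inflammation. The authors' deposited table gave 1 pooled FPKM value (fragments mapped, scaled to transcript length and library size) per genotype for each of 23284 genes, with a log2 fold, a test statistic, a p-value and an adjusted p. The values of the individual samples were not used here, so the read depth is unknown and no spread between replicates could be computed. Each log2 fold below is Srf KO over WT, and the ± after it is the standard error implied by the authors' fold and statistic. The labels do not say that the samples of a group came from separate animals, so the spread between samples may be technical. The settings of the authors' test are not given, so how far its p-values reflect that spread is not known.

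Srf itself was the first gene examined, as a check on the labels. In the authors' deposited table Srf (ENSMUSG00000015605.6, mm10 chromosome 17, 46546839 to 46556162, minus strand, 7 exons in its main annotated transcript) stood at 13.7 FPKM in WT and 0.439 FPKM in Srf KO. That is a log2 fold of -4.97 ± 0.27 in the authors' deposited table, or 31.3-fold lower, with an adjusted p listed as 0. The residual level was 3.19% of the WT level by the authors' deposited table. Which exons were deleted is not given in the sources used here, so the residual signal could not be placed within the gene.

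Many genes differed between the genotypes. Of 12634 genes that the authors tested, the authors' deposited table called 4486 (35.5%) at an adjusted p of at most 0.05, 2234 higher and 2252 lower in Srf KO. Among them 901 were at least 2-fold higher and 815 at least 2-fold lower. The smallest absolute log2 fold that was called was 0.43, and the median implied standard error was 0.24.

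Falls and rises were ranked among called genes at 1 FPKM or more in at least 1 genotype. By the authors' deposited table the genes with the largest falls among them were Hunk, a serine/threonine kinase (2.68 FPKM in WT, 0.0244 in Srf KO, log2 fold -6.78 ± 0.61), then Srf, the LIM homeobox gene Lhx1 (-4.77 ± 0.38) and the transporter gene Slc16a14 (-4.35 ± 0.47). Ctse, which encodes the aspartic protease cathepsin E, fell from 199 to 13.8 FPKM (-3.85 ± 0.19) in the authors' deposited table. Acta1, the skeletal muscle actin gene, fell from 47.5 to 3.48 FPKM (-3.77 ± 0.24), and Lima1, which encodes an actin-bundling LIM protein, fell from 8.92 to 0.788 FPKM (-3.50 ± 0.25), in the authors' deposited table. The others of the 10 largest falls there were 1810006J02Rik (-3.98 ± 0.53), Mpzl3 (-3.79 ± 0.34) and 1700071M16Rik (-3.45 ± 1.19), the last sharing its locus with another gene.

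Among called genes at 1 FPKM or more in at least 1 genotype, those with the largest rises were mostly at low levels in WT. In the authors' deposited table Xist, the non-coding RNA of the inactive X chromosome, whose locus overlaps its antisense gene, had a log2 fold of 8.31 ± 0.50 (0.0154 FPKM in WT, 4.92 in Srf KO). The chemokine gene Ccl8 (5.73 ± 2.04), the enkephalin precursor gene Penk (0.927 to 23.0 FPKM, 4.63 ± 0.29) and the kallikrein gene Klk1 (4.38 ± 0.90) followed in the authors' deposited table. Pf4, which encodes platelet factor 4, rose from 2.68 to 39.2 FPKM (3.87 ± 0.30) in the authors' deposited table. The ubiquitin-like gene Ubd (3.51 ± 0.62), Hebp1 (3.46 ± 0.30), the interferon-inducible GTPase gene Iigp1 (3.42 ± 0.32), Emp1 (3.39 ± 0.31) and 2210039B01Rik (3.28 ± 0.32) completed the 10 largest rises of such genes in the authors' deposited table. The table also called 4 genes listed at 0 FPKM in WT, among them the platelet collagen receptor gene Gp6 at 0.253 FPKM and Cdc42ep5 at 0.252 FPKM in Srf KO by the authors' deposited table.

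**Figure D1:**
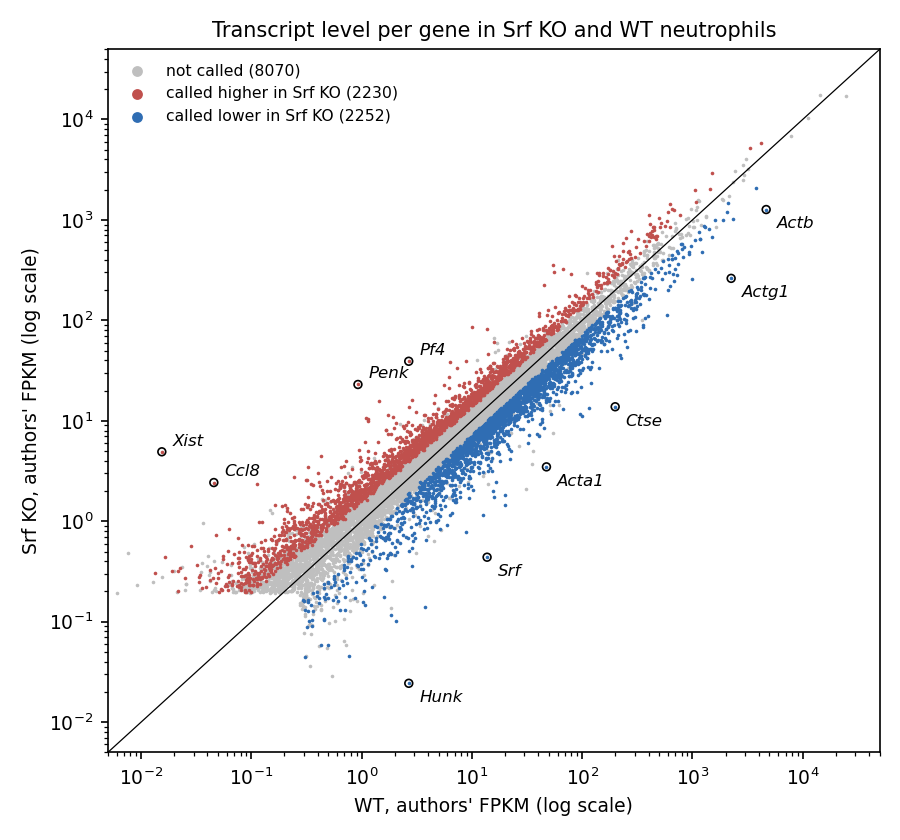
Authors' pooled FPKM of each tested gene with a value above 0 in both groups, WT on the horizontal and Srf KO on the vertical log axis, 1 point per gene, with the line of equal values. Srf, Actb, Actg1, Acta1, Ctse and Hunk lie below the line, and Xist, Ccl8, Penk and Pf4 above it; 2230 points are called higher and 2252 lower in Srf KO.

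SRF target genes of the actin cytoskeleton and contractile apparatus fell as a group. Of 38 tested members of this list, 23 were called lower and 4 higher (23 and 5 when adjusted over the list alone), with a median log2 fold of -0.86. Besides Acta1 and Lima1, the fall took in the 2 cytoplasmic actins, which are picked out here after their values were seen: Actb went from 4667 to 1268 FPKM (-1.88 ± 0.23) and Actg1 from 2246 to 262 FPKM (-3.10 ± 0.20) in the authors' deposited table. The members that rose furthest, Cald1 (3.45 ± 0.81), a caldesmon gene, and Fhl1 (3.17 ± 0.65), a LIM-domain gene, were at 0.274 and 0.684 FPKM in Srf KO by the authors' deposited table. The list was lower than other genes by limma's cameraPR (adjusted p = 4.16e-14), and its median lay below all 10000 random lists matched on expression. Of the listed genes, 12 also belong to another list used here.

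Genes of the immediate-early response, the other textbook class of SRF targets, fell too, with 14 of 26 tested members called lower and 4 higher (15 and 5 adjusted over the list alone). The phosphatase gene Dusp1 fell from 122 to 38.7 FPKM (-1.66 ± 0.19), the zinc finger gene Egr1 from 11.8 to 3.78 FPKM (-1.64 ± 0.22) and the AP-1 gene Junb from 34.5 to 12.2 FPKM (-1.50 ± 0.20) in the authors' deposited table. Nr4a2 rose (1.39 ± 0.47) but stood at 0.358 FPKM in Srf KO in the authors' deposited table. The median of the list was -0.48 and its cameraPR adjusted p was 0.000284. Among SRF and its cofactors, 4 of 6 tested genes were called lower and 0 higher, the deleted Srf itself included, the same counts as when adjusted over the list alone. The list passed cameraPR only with Srf in it (adjusted p = 5.57e-05 with Srf, 0.108 without, a setting added after seeing the data). Apart from Srf the called genes were Elk4 (-1.08 ± 0.23), Mkl1 (-0.89 ± 0.19, at a locus shared with another gene) and Elk1 (-0.83 ± 0.23) in the authors' deposited table.

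Genes of actin filament turnover fell as a group, with 31 of 53 tested members called lower and 4 higher (32 and 4 adjusted over the list alone). By the authors' deposited table Wdr1, a cofactor of cofilin in filament disassembly, fell from 245 to 62.4 FPKM (-1.97 ± 0.18), the formin gene Diap1 from 113 to 34.2 FPKM (-1.73 ± 0.18) and Coro1a, a leukocyte coronin gene, from 1231 to 479 FPKM (-1.36 ± 0.19). Cttn, at a locus shared with other genes, rose (1.92 ± 0.37) to 0.896 FPKM in the authors' deposited table. The median of the list was -0.52 (cameraPR adjusted p = 5.51e-07).

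Genes of leukocyte adhesion fell as a group, with 19 of 43 tested members called lower and 1 higher (20 and 1 adjusted over the list alone). The focal adhesion gene Zyx went from 354 to 86.0 FPKM (-2.04 ± 0.18), the P-selectin ligand gene Selplg from 304 to 108 FPKM (-1.49 ± 0.18), Itgal, the alpha chain of LFA-1, from 150 to 60.3 FPKM (-1.31 ± 0.20) and the talin gene Tln1 from 150 to 64.3 FPKM (-1.22 ± 0.19) in the authors' deposited table. The median of the list was -0.41 (cameraPR adjusted p = 6.62e-05). The cameraPR call only just held at a preset correlation of 0.10 (adjusted p = 0.0447) and after adjustment for length and expression (0.0489). Of the 47 genes listed, 11 also belong to another list used here. Of 28 tested genes of chemoattractant receptors and their proximal signalling, 17 were called lower and 4 higher (18 and 4 adjusted over the list alone), with a median of -0.59 (cameraPR adjusted p = 1.29e-05). The interleukin 8 receptor gene Cxcr1 fell from 4.93 to 1.03 FPKM (-2.26 ± 0.31) and the platelet activating factor receptor gene Ptafr from 51.9 to 11.7 FPKM (-2.15 ± 0.20) in the authors' deposited table. The complement receptor gene C3ar1 (1.98 ± 0.45) and the adenosine receptor gene Adora2a (1.59 ± 0.36) rose, both to under 1 FPKM, in the authors' deposited table.

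Genes that mark successive stages of neutrophil maturation moved in different directions. Genes of mature and circulating neutrophils fell, with 16 of 24 tested members called lower and 4 higher, counts that were the same when adjusted over the list alone (median -1.05, cameraPR adjusted p = 1.34e-06). The interleukin 1 beta gene Il1b fell from 257 to 54.5 FPKM (-2.24 ± 0.19) and the chemokine gene Ccl6 from 991 to 260 FPKM (-1.93 ± 0.19) in the authors' deposited table, each at a locus shared with 1 other gene. The stefin family genes BC100530 (2.30 ± 0.22) and Stfa2 (2.29 ± 0.21), near-identical copies whose reads cannot be assigned with certainty, rose in the authors' deposited table. Genes of primary granules, which are made at the promyelocyte stage, were called higher in 8 of 15 and lower in 2, also when adjusted over the list alone (median 0.60, cameraPR adjusted p = 0.0184). They included Ms4a3 (49.1 to 127 FPKM, 1.37 ± 0.19), Cst7 (1.34 ± 0.23), Nkg7 (1.13 ± 0.21) and the cathepsin G gene Ctsg (101 to 220 FPKM, 1.13 ± 0.19) in the authors' deposited table. The call of this list ended at a preset correlation of 0.05 (adjusted p = 0.0569) and after adjustment for transcript length (adjusted p = 0.171), where the median was 0.37, at percentile 99.99 of matched random lists. It held after adjustment for length and expression (adjusted p = 0.00380).

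Genes of secondary and tertiary granules split, with 10 of 21 tested members called lower and 3 higher (10 and 4 adjusted over the list alone). The membrane metalloproteinase gene Mmp25 fell from 117 to 33.0 FPKM (-1.83 ± 0.19), Adam8 from 291 to 105 FPKM (-1.46 ± 0.19) and the collagenase gene Mmp8 from 2320 to 1015 FPKM (-1.19 ± 0.22), whereas Orm1 rose from 55.1 to 305 FPKM (2.47 ± 0.19), in the authors' deposited table. The list median was -0.42, at percentile 4.26 of matched random lists, and its cameraPR adjusted p of 0.0487 rose to 0.134 at a preset correlation of 0.05 and fell to 0.00105 after length adjustment. The most abundant members, Ltf, Camp, Ngp, Lyz2, S100a8 and S100a9, were left untested by the authors because of too many reads. Of 7 subunit and regulator genes of the phagocyte NADPH oxidase, 3 were called lower and 0 higher, also over the list alone, among them Ncf1 (-0.67 ± 0.20) and Ncf4 (-0.51 ± 0.19) in the authors' deposited table. As a list they did not pass cameraPR (adjusted p = 0.127).

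Inflammatory and interferon genes moved apart. Of 28 tested genes of the inflammatory and NF-kB response, 11 were called lower and 4 higher (12 and 4 adjusted over the list alone; median -0.36, cameraPR adjusted p = 0.00159). Il1rn, which encodes the interleukin 1 receptor antagonist, fell from 117 to 13.4 FPKM (-3.12 ± 0.22) and the prostaglandin synthase gene Ptgs2 from 2.95 to 0.630 FPKM (-2.23 ± 0.28), while the chemokine gene Ccl5 rose from 7.35 to 33.9 FPKM (2.21 ± 0.28), in the authors' deposited table. The call of the inflammatory list ended at a preset correlation of 0.10 (adjusted p = 0.0773). Of 39 tested interferon-stimulated genes, 19 were called higher and 1 lower (19 and 2 adjusted over the list alone; median 0.28, cameraPR adjusted p = 6.1e-06). Ifi44 rose from 1.14 to 9.92 FPKM (3.12 ± 0.29), Lgals3bp from 5.62 to 22.5 FPKM, the tetherin gene Bst2 from 15.8 to 61.1 FPKM (1.95 ± 0.22) and Ifi27l2a from 187 to 546 FPKM (1.54 ± 0.19) in the authors' deposited table.

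Cell cycle genes rose as a group, with 21 of 34 tested members called higher and 0 lower (26 and 0 adjusted over the list alone; median 0.57, cameraPR adjusted p = 3.67e-07). Cdk1 (21.0 to 43.1 FPKM, 1.04 ± 0.19), the survivin gene Birc5 (1.04 ± 0.20), Ube2c (0.97 ± 0.19) and the stathmin gene Stmn1 (155 to 299 FPKM, 0.94 ± 0.18) had the largest folds of the list in the authors' deposited table. Cytosolic ribosomal protein genes rose too, with 48 of 82 called higher and 0 lower (51 and 0 adjusted over the list alone; median 0.60, cameraPR adjusted p = 5.34e-10). Rpl22l1 (1.23 ± 0.21), Rpl36a (1.04 ± 0.19), Rps24 (1.02 ± 0.19) and Rpl38 (1.01 ± 0.20), whose locus holds other genes too, led the called members in the authors' deposited table. These are short transcripts, and after adjustment for length the median of the list was 0.24, at percentile 100 of matched random lists. The list still passed cameraPR after that adjustment (adjusted p = 0.00105) and after adjustment for length and expression (adjusted p = 6.03e-12). Reads of ribosomal protein genes may be shared with their many processed pseudogenes.

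Genes of apoptosis and survival did not pass cameraPR as a list (adjusted p = 0.232), though their median of -0.39 lay at percentile 1.56 of matched random lists, with 3 of 22 called higher and 5 lower (4 and 7 adjusted over the list alone). Bcl2 rose (1.27 ± 0.34) in the authors' deposited table. The paralogs Bcl2a1d (0.88 ± 0.31) and Bcl2a1b (0.86 ± 0.30), near-identical copies whose reads cannot be assigned with certainty, were called higher in the authors' deposited table but not after adjustment for length. Heat shock and handling stress genes did not pass either (median 0.09, cameraPR adjusted p = 0.516), with 3 of 15 called higher and 2 lower, also over the list alone. Hspa1a (-1.24 ± 0.42), at 0.346 FPKM in WT, and Ddit3 (-1.08 ± 0.33) fell while the mitochondrial chaperonin genes Hspe1 (0.95 ± 0.22) and Hspd1 (0.73 ± 0.19) rose in the authors' deposited table. No mitochondrially encoded transcript was listed in the table, so that list was not tested.

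**Figure D2:**
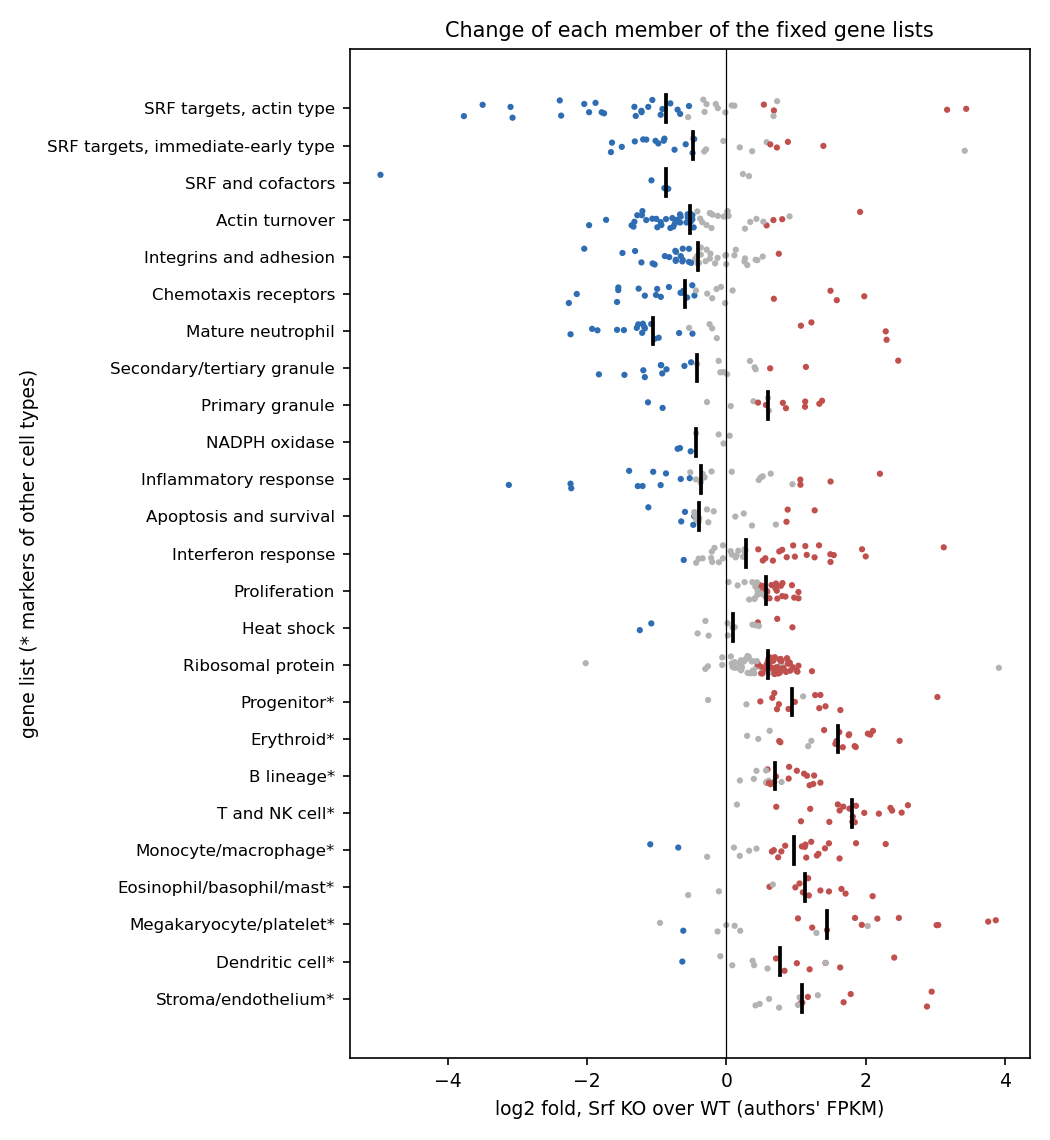
Log2 fold of each tested member that has a fold, 1 row per list, for the gene lists reported except the sex-linked list. Each point is 1 gene (red called higher, blue called lower, grey not called), with a black bar at the list median and asterisks for markers of other cell types. The SRF target list of actin type has its median at -0.86, mature neutrophil genes at -1.05, and the other-cell lists between 0.70 and 1.81.

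Markers of cell types outside the sorting gate were higher in the Srf KO samples for all 9 lists examined. T and NK cell markers were called higher in 18 of 19 and lower in 0, also over the list alone (median 1.81, cameraPR adjusted p = 6.12e-13), among them Cd4 (0.408 to 2.49 FPKM, 2.61 ± 0.31), Klrd1 (2.52 ± 0.36), Gzmb (2.38 ± 0.39) and the granzyme A gene Gzma (2.70 to 13.9 FPKM, 2.36 ± 0.30) in the authors' deposited table. Erythroid markers were called higher in 15 of 20 and lower in 0 (17 and 0 adjusted over the list alone; median 1.60, cameraPR adjusted p = 1.17e-09), with Car1, a carbonic anhydrase gene, going from 2.84 to 16.0 FPKM (2.49 ± 0.27) in the authors' deposited table. The most abundant tested marker of each of these lists rose far less there. Hbb-b2 of the erythroid list went from 128 to 158 FPKM, and Cd3d of the T and NK list from 13.5 to 15.0 FPKM. Megakaryocyte and platelet markers were called higher in 12 of 20 and lower in 1, also over the list alone (median 1.45, cameraPR adjusted p = 7.48e-06), led by Pf4 and by Gp5 (0.0624 to 0.846 FPKM, 3.76 ± 0.72) in the authors' deposited table. Rgs18, the most abundant tested member of that list, went down from 85.4 to 55.6 FPKM there. Of the 19 members with a fold, 12 reached 1 FPKM in at least 1 genotype, and the median WT level was 0.75 FPKM.

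Myeloid, progenitor and B lineage markers followed the same direction. Eosinophil, basophil and mast cell markers were called higher in 11 of 14 and lower in 0 (12 and 1 adjusted over the list alone; median 1.14, cameraPR adjusted p = 2.02e-06), with Mcpt8 rising by 1.71 ± 0.23 to 46.0 FPKM and Fcer1a by 2.10 ± 0.32 in the authors' deposited table. Monocyte and macrophage markers were called higher in 17 of 24 and lower in 2 (18 and 2 adjusted over the list alone; median 0.97, cameraPR adjusted p = 3.67e-07), with Spic, a transcription factor gene of red pulp and marrow macrophages, at 2.29 ± 0.29 and Vcam1 at 1.47 ± 0.20 in the authors' deposited table. Stem and progenitor markers were called higher in 13 of 16 and lower in 0, also over the list alone (median 0.94, cameraPR adjusted p = 6.47e-05), including Angpt1 (1.64 ± 0.29) and Flt3 (1.42 ± 0.27) in the authors' deposited table. B lineage markers were called higher in 15 of 22 and lower in 0 (19 and 0 adjusted over the list alone; median 0.70, cameraPR adjusted p = 2.02e-06), with Igll1 at 1.26 ± 0.27 and H2-Aa going from 34.2 to 78.4 FPKM (1.20 ± 0.21) in the authors' deposited table. Stromal and endothelial markers were called higher in 7 of 14 and lower in 0 (11 and 0 adjusted over the list alone; median 1.08, cameraPR adjusted p = 0.000253). Of these 14 genes, 6 reached 1 FPKM in at least 1 genotype. Dendritic cell markers were called higher in 7 of 14 and lower in 1, also over the list alone (median 0.77, cameraPR adjusted p = 0.000976). These rises stand beside the falls of mature neutrophil, adhesion and chemotaxis genes and the rises of cell cycle and interferon genes in the same samples.

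The groups also differed in sex-linked transcripts. Beside the rise of Xist, all 4 tested Y-linked genes were called lower in Srf KO, with log2 folds from -1.69 to -1.33 in the authors' deposited table, among them Kdm5d (-1.69 ± 0.27), Uty (-1.68 ± 0.29) and Ddx3y (13.5 to 4.23 FPKM, -1.67 ± 0.24). The counts adjusted over the list alone were the same. The list median (-1.67) and mean (0.39) differ in sign because of Xist, and the list did not pass cameraPR (adjusted p = 0.220). The labels do not give the sex of the animals. WT held Y-linked transcripts almost without Xist (0.0154 FPKM), whereas Srf KO held both Xist (4.92 FPKM) and Y-linked transcripts (Ddx3y at 4.23 FPKM). This pattern points to male material in WT and to both male and female material in Srf KO. Sex can therefore not be told apart from genotype in the calls. Without genes on X and Y, a setting added after seeing the data, 4350 genes were called, but this does not remove any effect of sex on genes of other chromosomes.

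Over the 27 lists tested, 23 had a cameraPR adjusted p under 0.05, 13 of them higher and 10 lower in Srf KO. With Srf left out of its own list, 21 did. The correlation between genes could not be estimated from pooled values. At a preset correlation of 0.05 the calls of 21 lists held, and at 0.10 those of 19, the SRF target list included (adjusted p = 0.000218 at 0.10).

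The folds followed transcript length, which bears on every list above. The median log2 fold fell from 0.38 in the decile of shortest transcripts (median 761 nt) to -0.28 in the decile of longest (median 7409 nt). Across 12364 genes, which are not independent replicates, Spearman's rho of fold on length was -0.24. After the folds were adjusted for length, 4087 genes were called, of which 3464 were among the 4486. The median of the SRF target list of actin type was then -0.95 and that of mature neutrophil genes -1.05. The fold also followed expression level, with a median of 0.71 in the decile of genes with the lowest FPKM and -0.15 in the highest.

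**Figure D3:**
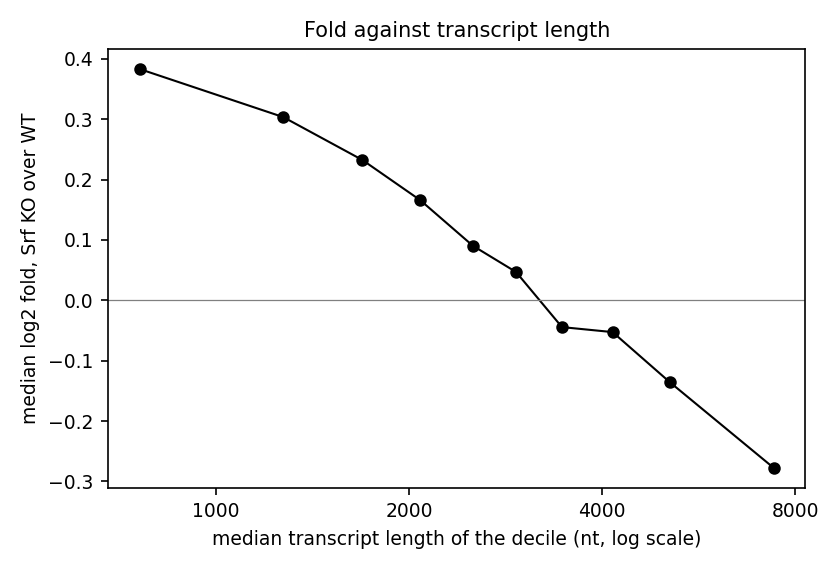
Median log2 fold (Srf KO over WT) of genes grouped into deciles of transcript length, plotted against the median length of each decile on a log axis, 1 point per decile. The median falls from 0.38 at 761 nt to -0.28 at 7409 nt.

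Changes at the level of transcripts, promoters and coding sequences mostly mirrored the gene table. The authors' deposited tables called 4012 of 14766 tested isoforms (1938 higher, 2074 lower), 4072 of 13042 groups of transcripts sharing a start site (1968 higher, 2104 lower) and 3948 of 13066 coding sequences (1879 higher, 2069 lower). Of the called isoforms 327 lay in 282 genes that were not called as genes, and 51 genes had isoforms called in opposite directions. The same counts were 159 in 137 genes and 25 for start-site groups, and 236 in 209 genes and 33 for coding sequences.

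Among start-site groups called in genes that were not called, Sgk1, a serum- and glucocorticoid-inducible kinase gene, had a group going from 0.346 to 10.4 FPKM (4.92 ± 1.61, adjusted p = 0.0110) while the gene as a whole was at 29.6 FPKM in WT and 25.1 in Srf KO, in the authors' deposited tables. A start-site group of Wash, a gene of endosomal actin regulation, went from 6.31 to 0.552 FPKM (-3.51 ± 0.77, adjusted p = 6.55e-05) while the gene stayed uncalled (-0.04, adjusted p = 0.914), in the authors' deposited tables. A start-site group of Eps15, an endocytic adaptor gene, went from 0.376 to 21.1 FPKM (5.81 ± 2.02, adjusted p = 0.0171) against a gene fold of -0.09 in the authors' deposited tables. The standard errors of the rises in Sgk1 and Eps15 exceed 1.5 on the log2 scale.

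Genes near Srf were examined for a strain difference linked to the targeted locus. Within 5 Mb of Srf, 22 of 78 tested genes were called (28.2%), against 4463 of 12555 elsewhere (35.5%), a difference that did not pass a two-sided Fisher's exact test (odds ratio 0.712, exact p = 0.193). Within 2 Mb called genes were fewer, 14 of 64 (odds ratio 0.507, exact p = 0.0253).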

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

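Pooled values set the main limits. No paired analysis was possible because the tables hold 1 value per genotype and the labels give no shared replicate numbers; for the same reason no sample could be left out, and depth is unknown. The count of called genes (4486) stayed within 1.5 times under 11 of 13 alternatives, from 3019 to 5447, the length adjustment and the removal of X and Y having been chosen after seeing the data. Some of these alternatives only left out a small set of genes, so their counts could hardly leave that range. The genes left out were those at 0 in 1 group (4482 calls kept), on X and Y (4350), or in the other-cell, sex-linked and ribosomal lists (4319). Centring the folds (shift 0.08) and recomputing the adjusted p are not counted, since neither could change these calls. The count was 1720 with a 2-fold minimum, the 4 genes at 0 in WT included, and 2799 with a log2(FPKM + 1) fold of at least 0.58, since both add a requirement. The share of calls that were higher in Srf KO went from 49.8% to 38.0% with a filter at 5 FPKM. Isoforms, TSS groups and coding sequences called were 2620, 2675 and 2604 at an adjusted p of 0.01 and 1757, 1596 and 1603 with a 2-fold minimum. The Srf fold was -3.36 on the log2(FPKM + 1) scale, which understates changes at low values; the 3 feature tables repeat the gene's values for Srf.

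The SRF target list was lower with an adjusted p between 1.24e-15 and 0.000218 under its 8 alternatives. Of the other lists that passed and are reported, the secondary and tertiary granule list lost its call at preset correlations of 0.05 (adjusted p = 0.134) and 0.10 (0.222), on log2(FPKM + 1) folds (0.0620), with a filter at 1 FPKM (0.113) and after adjustment for length and expression (0.235), but not after length adjustment alone (0.00105). The primary granule list lost it at correlations of 0.05 (0.0569) and 0.10 (0.115) and after length adjustment (0.171), but not after adjustment for length and expression (0.00380). The inflammatory list lost it at 0.10 (0.0773). With Srf left out, a setting added after seeing the data, the list of SRF and its cofactors lost its call (0.108), as did the secondary and tertiary granule list (0.0509), whose members and unadjusted p were unchanged, through the adjustment over the lists. A higher preset correlation widens the null by construction; for the other settings the cause was not tested. Near Srf the odds ratio was below 1 in each window, and passed the exact test only within 2 Mb (odds ratio 0.507, p = 0.0253), where the cause was not tested. Of 118 genes with a fold that the naming rule picked, 2, Bcl2a1d and Bcl2a1b, lost their call after length adjustment, and 59 moved by at least their implied standard error on the log2(FPKM + 1) scale.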

Other observations

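Of the tests in this part, the comparison across other-cell lists and the spread of folds among mature neutrophil genes were chosen after the result was seen. A list of 15 granulocyte precursor genes and a list of 14 late neutrophil genes were drawn up after the fixed lists had been tested, before the folds of these genes were examined. By the authors' calls, 10 of 15 precursor genes were called higher and 1 lower in Srf KO, and by the authors' deposited table these included the chaperone gene Npm1 (76.7 to 173 FPKM, 1.18 ± 0.20), the histone variant gene H2afz (439 to 843 FPKM, 0.94 ± 0.19) and the granulocyte transcription factor gene Gfi1 (0.82 ± 0.20). Cebpe, the transcription factor gene of granule protein expression, was at -0.10 ± 0.18 and was not called in the authors' deposited table. Cebpa, a further transcription factor gene of the precursor list, was at -0.15 ± 0.20 and was not called there either. Of 12 tested late genes, 1 of which is also in the chemotaxis list, 11 were called lower and 0 higher, with Cd101, a surface marker of mature neutrophils, falling from 94.7 to 11.7 FPKM (-3.02 ± 0.20) and Cd300ld from 144 to 33.3 FPKM (-2.11 ± 0.18) in the authors' deposited table. In length-adjusted folds the precursor median was 0.52 and the late median -0.96.

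Mature neutrophil genes were lower in Srf KO (median -1.05 over 24 genes). The length trend as the whole cause is argued against, since the list was as low after length adjustment (median -1.05, cameraPR adjusted p = 3.2e-09). Dilution of neutrophil RNA by RNA of other cell types, as the whole cause, would lower every member that those cells lack by 1 factor. The SD of member folds was 1.22 against a median standard error of 0.19. Called higher were 4 members, the near-identical copies BC100530 and Stfa2 among them. Which members the other cells also express was not tested, so dilution as part of the cause stays open. A larger share of less mature cells of the neutrophil lineage among the sorted Srf KO cells is a candidate explanation: the precursor list lay at percentile 100 of matched random lists and the late list at percentile 0.05. The precursor list, however, holds many general growth and chromatin genes, such as Npm1 and H2afz. It was also drawn up after the cell cycle list had been seen to rise, so its percentile does not single out the neutrophil lineage. Loss of SRF acting on these genes within mature cells was not tested and stays open, as does RNA of dividing progenitors of other lineages.

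Markers of 9 other cell types were higher in Srf KO. A general rise of low-abundance transcripts as the whole cause is argued against, because 9 of the 9 lists lay above the central 95% of random lists of like expression. The length trend of the libraries is argued against in the same way, with 9 of 9 lists above it after adjustment. A lower share of neutrophils raising every other type alike was predicted to give the lists similar folds. They differed, with list medians from 0.50 to 1.81 (permutation p = 0.0001 in a Kruskal-Wallis test over 152 genes that belong to a single list). The difference cannot decide the question, because markers that neutrophils also express would rise less and the folds also follow expression level. A lower share of neutrophils, unequal carry-over of cell types through the gate, a different marrow composition in Srf KO mice, and expression of these genes in the neutrophils themselves remain open. The highest markers, such as Ly6c2 (1144 FPKM in WT, 1544 in Srf KO in the authors' deposited table), are also expressed by neutrophils.

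Shorter transcripts were higher and longer transcripts lower in Srf KO. The fixed gene lists as carriers of the trend are argued against by a rho of -0.23 over the 11719 genes outside them. Expression level standing in for length is argued against by a median rho of -0.38 within 10 expression bins, which ranged from -0.51 to 0.02. RNA integrity or fragment size differing between the groups' libraries may account for it: within 351 genes the log2 fold changed by -0.20 per doubling of length from the shortest to the longest isoform (95% bootstrap interval -0.36 to -0.06), against -0.22 across genes. No library quality values were used, so this stays a hypothesis, and a biological cause that acts on long isoforms was not tested.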
